A study of Mus musculus with 217 samples.

How the data were processed

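Single cells were taken from the microdissected tibial growth plate of wild-type C57/BL mice at postnatal day 7. Per the labels' protocols, polyA RNA of each cell was turned into full-length cDNA with SMARTer chemistry and made into libraries with Nextera XT. The submitters' processing notes name TopHat, a spliced aligner, and the mouse genome build mm10. The quantifier, the annotation, the filters and the unit of abundance are not given in the sources used here.

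The deposited values are on a log2 scale, 1 column per cell, from 0 to 15.14, and 62.3% of them are exactly 0. The base was inferred from the values: back-transformed totals per cell had a coefficient of variation of 7.33% with base 2, 14.8% with base e and 190.5% with base 10, and a pseudocount of 1 was taken because the lowest value is 0. With base 2 the totals ran from 394406 to 616257 (median 476331), so the values were scaled for depth before deposit, and depth per cell is unknown. Each of the 9739 genes is above 0 in at least 10 cells, so that genes of rare cells can be missing. The 1 row with no gene name holds no values and was left out. An exact 0 can be a failed estimate as well as a gene that was not expressed. Some gene names had been turned into dates and were left as they stand.

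All 217 columns were matched to cells by name. The fixed design used all 217 cells. After the data were seen, columns with r above 0.95 were averaged as repeats, and 1 column that correlated above 0.75 with at least 2 other sets was left out as a mixture, which left 187 profiles. The repeats kept apart and the mixed column kept in were run as alternatives. No doublet caller was run. No animal is named, so no test or p-value was computed. An SD over 1000 resamples of profiles was taken for the resting and hypertrophic correlation and for the Ihh and Col10a1 ratio. It treats cells as independent and leaves out spread between animals.

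The measures, gene lists and markers were fixed before the data were examined, as were the alternatives other than those for repeats, for the mixed column and for the leading genes of clusters. Detection meant a back-transformed value of at least 1. Shares of profiles have 95% exact Clopper-Pearson intervals. The pooled share for other cell types is the median over the measured genes of the endothelial, macrophage, osteoclast, neutrophil, B and T cell, red blood cell, muscle, marrow stromal, osteoblast, articular and perichondrial lists. For clustering, the 1000 genes of highest variance among those detected in at least 5% of profiles were centred, 10 principal components were kept, and Ward linkage was applied with the number of clusters from 3 to 8 that had the highest mean silhouette. The silhouette was 0.155 with 5 clusters and 0.154 with 3. Clusters were named only from the marker lists. Cluster 5 was left out of the zone axis, the mean z of the hypertrophic list minus that of the resting list. Genes detected in at least 20% of profiles, outside both axis lists, were correlated with it by Spearman's rho. A list was described by its median and the percentile of that median among 10000 random lists drawn from the 100 genes on each side in mean level, and stood apart below 2.5 or above 97.5. Random lists were drawn gene by gene, so their range can be too narrow for a list whose genes vary together. Correlations are across cells of 1 sample, which are not replicates.

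The genes named were the 10 with the largest mean difference per cluster among genes detected in at least 50% of its profiles, the 15 highest and 15 lowest along the axis, the 10 of highest mean, 17 fixed genes, and the members of largest value of each list described. Other names were chosen after their values were seen: Spry2, Fos and Atf3 for cluster 3, some list members given as examples, and those in the closing section. One gene that the rule selects is not reported here.

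The alternatives were detection of any value above 0 or of at least 10, leaving out the 10% of profiles with fewest genes, 2000 variable genes, k-means, a pseudocount of 0.1, leaving out cell cycle genes, regressing out genes detected, upper-quartile scaling, another axis and leaving cluster 5 out of the profiles that a cluster was compared with. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, NetworkX 3.6.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data, made by shuffling genes over profiles or adding noise to single profiles. Of genes given a correlation of 0.6 with an axis, 95% reached a rho of 0.4 among 5385 genes, and no shuffled gene did. Of random lists, 3% fell outside the range. Shuffling removes the correlation between genes, so this 3% does not cover lists of genes that vary together. All 20 simulated repeats and the simulated mixture were found, no other column was called, and a simulated cluster was recovered in full. That cluster was made in shuffled genes, without a link to genes detected. Its genes were raised by more than the leading differences of clusters 1, 2 and 4. Its recovery therefore does not show that clusters like these can be recovered.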

Results

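Gene expression was measured in single cells from the tibial growth plate of wild-type mice at postnatal day 7. The growth plate is the cartilage in which chondrocytes pass from a resting zone through columns of flat dividing cells to prehypertrophic and hypertrophic cells, and the title of the study names the reconstruction of this sequence as its aim. The 217 deposited columns carry the same labels, and no animal, litter or plate is named for any of them. All cells were therefore treated as 1 sample of 1 group, and no test was possible. Each SD below is a spread over cells, except those named as between repeats or over resamples of profiles. Each 95% exact (Clopper-Pearson) interval covers counting error only. Sequencing depth is unknown, because the deposited values were already scaled.

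Some columns were nearly the same as others. Of the 217 columns, 52 fell into 23 sets (17 of 2 columns and 6 of 3) whose members correlated at r = 0.964 to 0.994 over 9739 genes, whereas the 23185 other pairs reached at most 0.686. These columns were treated as repeats of one cell. When pairs were chosen on 4870 of the genes alone, the same 35 pairs were found, and a median of 5.73% of 1676 genes not used to choose them were detected in only 1 column, against 45.7% over the 23185 other pairs. Each set was averaged and counted as 1 profile. One further column, which resembled the sum of 2 other profiles, was left out, and 187 distinct profiles remained. The SD between repeats was 0.48 on the log2 scale for genes with values of 4 to 6 and 0.37 for values of 8 to 10. It was 0.64 for Col10a1, against an SD of 4.46 between all 187 profiles. If repeats share the cDNA of one cell, their SD leaves out error from capture and cDNA synthesis. The 2 values then do not divide technical from biological spread.

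**Figure D1:**
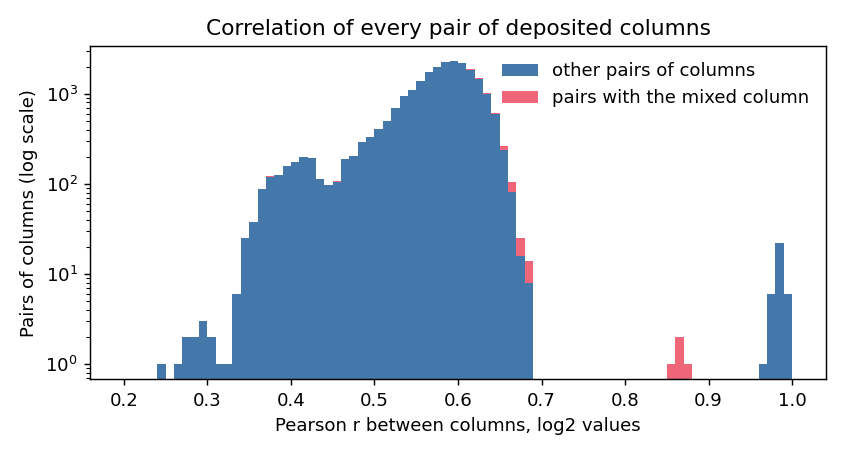
Pearson correlation of log2 values (horizontal axis) for every pair of the 217 deposited columns, with the number of pairs on a log scale. Pairs within sets of repeats lie at 0.964 and above and all ordinary pairs at 0.686 or below; the pairs between them belong to the mixed column.

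A profile held a median of 3433 detected genes (mean 3376 ± 595 SD, n = 187 profiles, range 1326 to 4994), with detection set at a back-transformed value of at least 1. The genes of highest mean were Eef1a1 (13.03 ± 0.39 SD), a translation elongation factor, Lect1 (12.61 ± 2.85), which encodes the cartilage protein chondromodulin, and Sparc (12.45 ± 0.79), a matrix glycoprotein of bone and cartilage. They were followed by Rps3a1, Actb, Sdc4, Rpl9, Rpl41, Ppia and Ubb, with means of 11.84 down to 11.44.

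Cartilage genes were detected in nearly all profiles. The median share over the 18 measured members of the chondrocyte list was 94.7%. Sox9, the transcription factor that specifies chondrocytes, was detected in 182 of 187 profiles (97.3%, interval 93.9 to 99.1%). Acan, which encodes the proteoglycan aggrecan, was detected in 177 (94.7%, 90.4 to 97.4%) at a median of 9.13, and Col11a1, a cartilage collagen, in 98.4% at a median of 11.21. Col2a1, which encodes the main collagen of cartilage, was an exception: it was detected in 38 profiles (20.3%, 14.8 to 26.8%) and never exceeded 3.14. Sox5 and Sox6, partners of Sox9, were also low, with detection in 10.2% and 1.07% of profiles. Fgfr3, a receptor that restrains chondrocyte division, was detected in 13 profiles (6.95%, 3.75 to 11.6%) and Runx2, a regulator of hypertrophy and bone formation, in 20 (10.7%, 6.66 to 16.0%). Pthlh, Pth1r, Prg4 and Ptprc were not analysed here.

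The zone lists differed in how often their genes were detected. The prehypertrophic list had a median share of 39.6% over 9 measured genes, the hypertrophic list 28.9% over 13, the resting list 25.9% over 10 and the flat columnar list 70.9% over 10. The columnar list holds genes that most chondrocytes carry, such as Col9a1 (95.2%) and Fmod (94.7%), beside Fgfr3 and Pcp4 (6.95% and 7.49%). Col10a1, the collagen of hypertrophic cartilage, was detected in 139 profiles (74.3%, 67.4 to 80.4%). Ihh, the hedgehog ligand of prehypertrophic cells, was detected in 62 (33.2%, 26.5 to 40.4%). Spp1 and Ibsp, which encode acidic proteins of mineralized matrix, were detected in 27.3% and 24.6%, and Mmp13, a collagenase, in 9.09%. Among resting genes, Ucma was detected in 56.1% and Sfrp5 in 35.3%.

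Markers of other cell types had a median share of 14.7% over the 40 measured genes of the 11 lists of other types. Medians were 5.35% for the 2 measured endothelial genes, of which Pecam1 was detected in 7 profiles (3.74%, 1.52 to 7.56%), and 5.88% for 5 macrophage genes. The B and T cell list had 1 measured gene, at 3.21%. Medians were 14.4% for 5 muscle genes, 16.6% for 5 marrow stromal genes and 9.36% for 2 articular genes. The osteoblast list reached 21.4% over 12 genes and the perichondrial and fibroblast list 26.2% over 8, and both hold genes that chondrocytes share, such as Sparc at 100% and Lum at 97.3%. Of the 2 measured osteoclast genes, Ctsk was detected in 68.4% and Mmp9 in 4.28%. Neutrophil and red blood cell genes were not analysed here. The median over all 40 genes was 8.56% with detection set at a value of 10. Every gene analysed is above 0 in at least 10 of the 217 columns, so the lowest of these shares lie near the floor that this sets. They describe the measured genes only and do not count cells of a type.

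Clustering on the 1000 most variable genes gave 5 clusters. The genes below describe the clusters that were built from them and were not tested. Cluster 5, with 12 profiles (6.42%, interval 3.36 to 10.9%), was osteoblast-like on average, although not every profile carried the bone genes: Ibsp was detected in 10 of the 12, Col1a2 in 9 and Col1a1 in 8. Its leading genes included Ibsp (9.75 ± 5.64 SD against 1.21 in all other profiles), Col1a1 (7.97 ± 6.08 against 0.57), Tmsb4x, Car3, Lgals1, Serpine2, Ifitm3, Serpinf1 and Col1a2. Of these, Col1a1 and Col1a2 encode the collagen of bone, and Ifitm3 is an interferon-induced gene. The osteoblast list was higher by a median of 2.93 (10 of 12 genes higher), above the upper limit of 0.30 for random lists of the same level. The chondrocyte list was lower in all 18 genes, with a median difference of -8.00. The list of matrix proteases and inhibitors was higher by 1.64 and the perichondrial list by 1.41, and the osteoblast and perichondrial lists had the same median share there, 54.2%. The hypertrophic list was also higher, by a median of 0.80 (7 of 13 genes higher, upper random limit 0.31), and it shares Ibsp and Dmp1 with the osteoblast list. Immediate-early and heat shock genes, which can respond to tissue dissociation, were higher by 0.72 (16 of 19). The 2 measured endothelial genes had a median share of 29.2% in cluster 5, against 2.99%, 3.23%, 8.33% and 0% in clusters 1 to 4.

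Cluster 3, with 30 profiles (16.0%, 11.1 to 22.1%), was hypertrophic-like. Col10a1 led it at 10.70 ± 1.89 SD against 5.36 in all other profiles and was detected in 100% of its profiles. Ptgis, Ibsp (5.10 ± 4.74 against 1.12), Cd200, Dhrs7, Cep85l, Smim5, Klf3, Hist1h1c and Id3 followed, with differences of 4.17 down to 3.36. Cd200 belongs to the resting list. The prehypertrophic list was higher by a median of 1.36 (8 of 9 genes) and the hypertrophic list by 1.20 (12 of 13), against upper random limits of 0.84 and 0.78. The osteoblast list, of another cell type, was also higher, by 0.95 (11 of 12, upper random limit 0.69). It is not independent of the zone lists: Ibsp and Dmp1 are also hypertrophic members and Sp7 is a prehypertrophic one. Ihh averaged 4.41 ± 2.98 SD there, and 1.29 and 1.40 in clusters 1 and 2. Genes of the BMP pathway were higher by 1.08 (14 of 16) and proteoglycan sulfation and chain synthesis genes by 0.99 (16 of 18). Cyclin-dependent kinase inhibitors and D cyclins were higher by 1.13 (6 of 8). This last list shares Cdkn1a and Cdkn1c with the hypertrophic list, and its difference without them was not computed. FGF pathway genes were lower by a median difference of -0.35 (6 of 7 lower), with Spry2, a feedback inhibitor of this pathway, at 2.44 ± 2.17 SD. Immediate-early and heat shock genes were higher in the same cluster by 1.31 (17 of 19), with Fos at 8.90 and Atf3 at 7.04. The median of all genes differed by -0.14, 0.12, 0.21, -0.30 and -0.17 in clusters 1 to 5, and by 0.30 in cluster 3 after upper-quartile scaling. Relative to that shift, no list with a median difference given for clusters 3 and 5 changed direction in the settings tried. The endothelial list, with 2 measured genes, was not among them. With genes detected regressed out, however, the differences in cluster 3 relative to the shift went from 1.15 to 0.57 for prehypertrophic, 0.74 to 0.49 for osteoblast, 1.10 to 0.64 for immediate-early, 0.87 to 0.10 for BMP, 0.78 to 0.21 for sulfation and chain synthesis and -0.56 to -0.90 for FGF genes.

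The other 3 clusters all carried the cartilage genes, with a median of 100% of profiles for the chondrocyte list. Cluster 1 (67 profiles, 35.8%, interval 29.0 to 43.2%) was chondrocyte-like, with small leading differences: Epyc, a small proteoglycan of cartilage, was higher by 1.66, Hapln1, which links aggrecan to hyaluronan, by 1.62, and Panx3, a prehypertrophic channel gene, by 1.52. Rbm26, Sc4mol, Btg3, Sema3d, Lect1, Spry2 and Scrg1 followed, with differences down to 1.41. For cartilage genes much of this came from the profiles of cluster 5, where they were lower: against the other profiles outside cluster 5, Epyc was higher by 0.66, Hapln1 by 0.66 and Lect1 by 0.37. Sema3d (1.41), Btg3 (1.30), Rbm26 (1.27) and Spry2 (1.11) changed less. Immediate-early and heat shock genes were lower in cluster 1 (median difference -0.55, 18 of 19 lower), as were matrix proteases and inhibitors (-0.48, 14 of 16) and osteoblast genes (-0.36, 11 of 12). Relative to the shift of all genes and with cluster 5 left out, these differences were -0.27, -0.01 and 0.03. S phase genes (-0.37, 13 of 15 lower) and G2/M genes (-0.23, 14 of 15) were lower in cluster 1 as well. Relative to the shift, their differences ran from -0.35 to -0.15 and from -0.15 to -0.01 over the settings tried. Cluster 2 (62 profiles, 33.2%, 26.5 to 40.4%) had no marker among its leading genes and was left unnamed. These were F3, the gene of tissue factor (5.55 ± 3.60 SD against 2.68), Fbln7, Impact, Plet1, Inhba, Moxd1, Sox11, Rqcd1, Trappc6b and Hmga2, with differences of 2.88 down to 2.20. Hypertrophic genes were lower in it (median difference -0.44, 10 of 13 lower), and so were osteoblast (-0.42, 10 of 12), prehypertrophic (-0.14, 7 of 9) and mineralization genes (-0.15, 12 of 16), the last of which had a median of 0.01 after upper-quartile scaling. The chondrocyte list was higher by 0.76 (15 of 18) and the flat columnar list by 0.79 (7 of 10) against all other profiles, but these differences were -0.005 and -0.02 with cluster 5 left out, whereas the chondrocyte list in cluster 1 went from 0.88 to 0.29. Cluster 4 (16 profiles, 8.56%, 4.97 to 13.5%) was also unnamed: Ank, Cct4, Tomm34, Map1b, H19, Yrdc, Slc4a7, Ywhag, Api5 and Sdad1 led it by 2.37 down to 1.48. Without the 10% of profiles with fewest genes, which leaves 5 profiles in it, 1 of these 10 genes still led and 1 was lower than in the other profiles. Its profiles held a median of 2368 detected genes, against 3093 in cluster 1, 3725.5 in cluster 2, 3982.5 in cluster 3 and 2642 in cluster 5. The first component correlated with genes detected (r = 0.878, across profiles of 1 sample), and regressing genes detected out of every gene left 3 clusters. In that setting 25 of the 30 profiles of cluster 3 and all 12 of cluster 5 stayed together, while 64 profiles of cluster 1, 62 of cluster 2 and 15 of cluster 4 lay in 1 cluster of 144. With a pseudocount of 0.1, the 12 profiles of cluster 5 shared a cluster of 29 with 15 of cluster 4, and with 2000 variable genes 8 of the 12 stayed together. With repeats kept apart, 28 of the 33 columns of cluster 3 lay in a cluster of 71 with 42 of cluster 2.

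**Figure D2:**
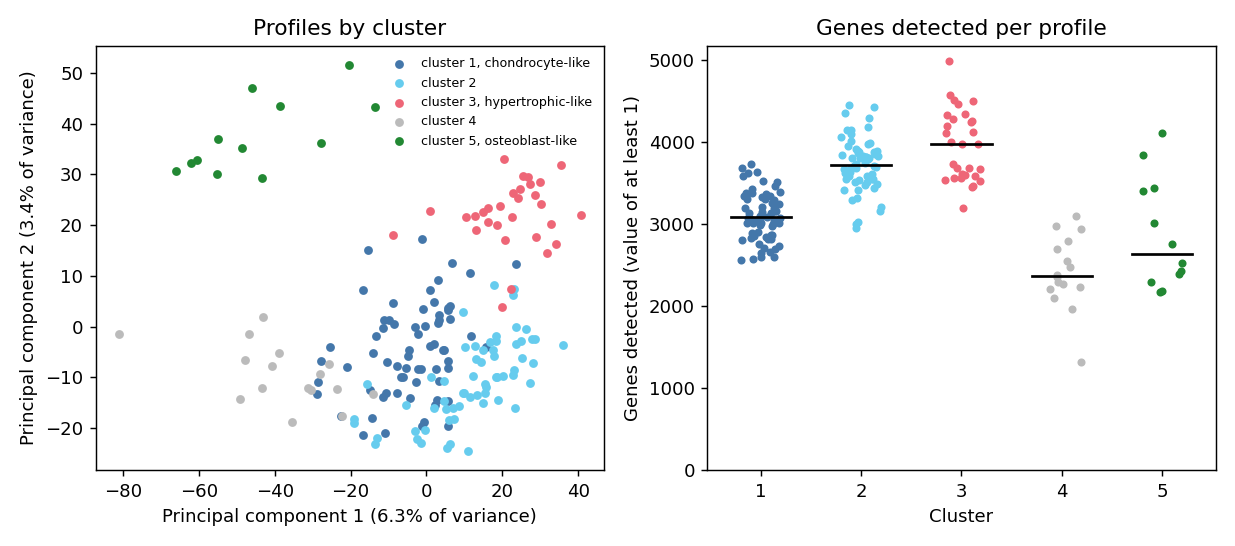
Left, the 187 profiles on the first principal components (6.31% and 3.43% of the variance), coloured by cluster. Right, genes detected in each profile, with the cluster median as a line; medians run from 2368 in cluster 4 to 3982.5 in cluster 3.

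**Figure D3:**
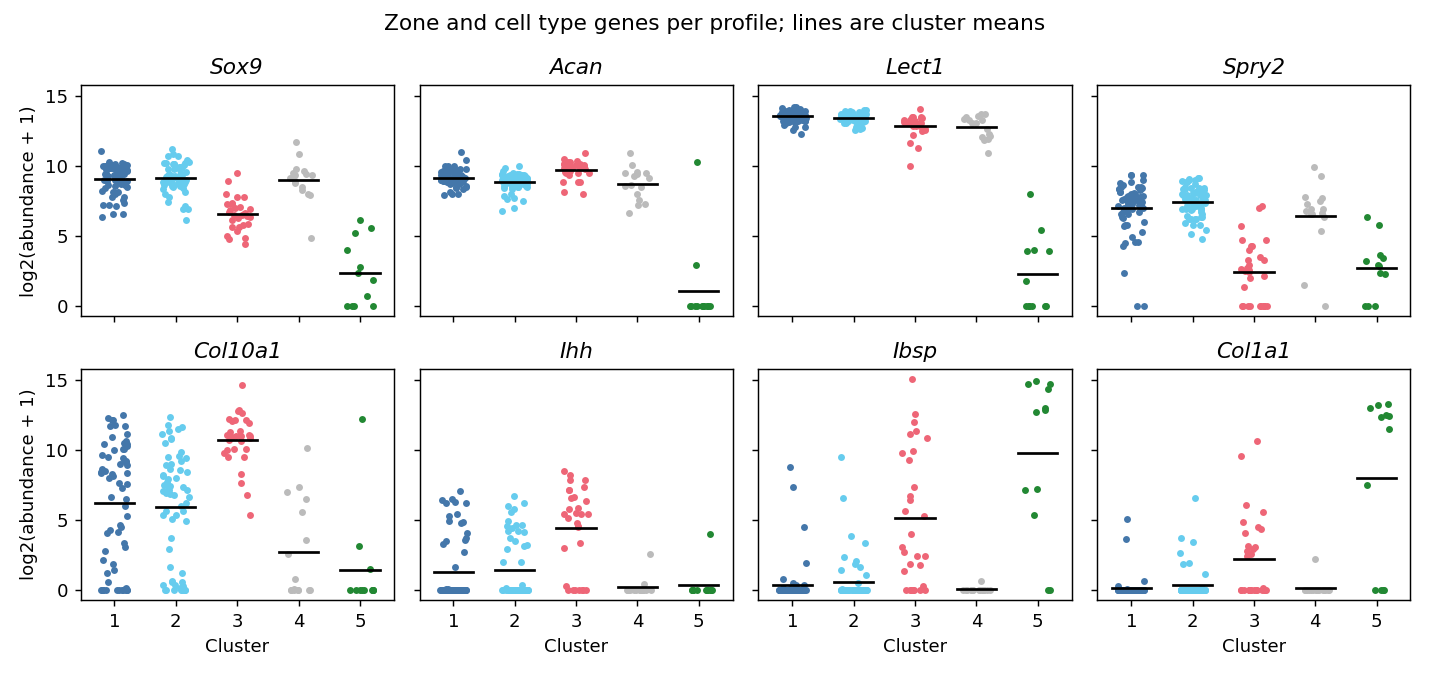
Level of 8 genes, log2(abundance + 1), in each of the 187 profiles by cluster, with the cluster mean as a line. Col10a1 averages 10.70 in cluster 3, and Col1a1 7.97 in cluster 5, where Lect1 averages 2.26.

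The mean scores of resting and hypertrophic genes were not opposed across the chondrocyte profiles. Over the 175 profiles outside cluster 5, the mean z of 10 resting genes and that of 13 hypertrophic genes correlated positively, at r = 0.215 ± 0.072 (SD over 1000 resamples of profiles) and rho = 0.184. Random pairs of lists of the same level gave a median r of 0.187 and a 95% range of 0.028 to 0.340, and the observed value stood at percentile 63.8. The correlation given genes detected per profile was 0.0175. Some members were rarely detected in these profiles: Gas1 in 2.29%, Apoe in 5.71% and Barx2 in 6.29% for the resting list, Dmp1 in 6.86% and Mmp13 in 8% for the hypertrophic list. Every member has the same weight, so the correlation describes these scores and cannot exclude that the zones are opposed. On the axis made from these lists, hypertrophic minus resting score, the resting genes Ucma and Sfrp5 had rho values of -0.48 and -0.47, whereas Cd200 and Nt5e, which are subtracted in the same score, had 0.25 and 0.18.

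**Figure D4:**
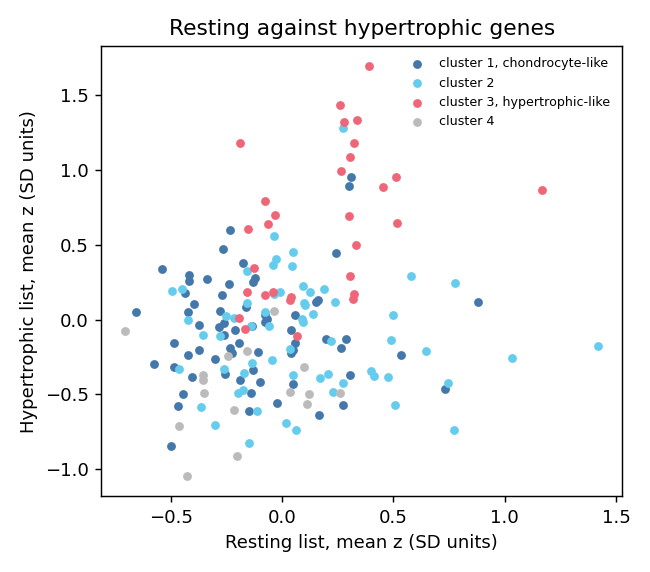
Mean z of the hypertrophic list against mean z of the resting list in the 175 profiles outside cluster 5, coloured by cluster. The 2 scores correlate weakly and positively (r = 0.215).

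Prehypertrophic genes, which are not part of this axis, went with its hypertrophic end. Their median rho was 0.22 (all 9 above 0), beyond the random limit of 0.11, with Bmp6 (0.39), Panx3 (0.38) and Mef2c (0.27) the highest. Osteoblast genes had a median of 0.16 (10 of 10 above 0, with Sparc at 0.35 and Smpd3 at 0.31) and mineralization genes 0.12 (10 of 12). The lists are not independent. Sparc, Smpd3 and Bglap are in both of these, the osteoblast gene Sp7 is also a prehypertrophic one, and Bmp6 is also a BMP pathway gene. BMP and TGF-beta pathway genes had medians of 0.10 each, and immediate-early and heat shock genes also 0.10. G2/M genes had a median of -0.09 (1 of 15 above 0), below the random limit of -0.03, with Cdk1 at -0.23 and Top2a at -0.21. S phase genes had a median of -0.05 (3 of 15 above 0, with Mcm3 at -0.26). Each G2/M gene was detected in at most 11.4% of these profiles. The random limit does not allow for genes that vary together in few profiles, so the 15 genes are not separate observations. The BMP, TGF-beta and immediate-early lists lay within the random range given genes detected per profile, where the chondrocyte (partial median 0.09) and the hypoxia and glycolysis lists (0.07) lay above it. After upper-quartile scaling, the mineralization, BMP and immediate-early lists lay within the range. With members detected in at least 20% of profiles, so did the S phase (-0.03) and TGF-beta lists (0.01). The G2/M list could not be run in that setting, since its most widely detected member, Cdc20, was found in 11.4% of profiles. Without correction for genes detected, the other 20 lists lay within the random range, among them the WNT (0.05), FGF (0.06), IGF (0.04) and Notch (0.10) pathways.

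Few single genes followed the axis closely. Of 5424 genes, 2 had a rho of at least 0.4, namely Ccdc80 (0.48) and Lmcd1 (0.42), and 1 had a rho of at most -0.4, Lmna (-0.41), which encodes a nuclear lamina protein. Given genes detected per profile, Ccdc80 alone passed (0.44), with Lmcd1 at 0.38 and Lmna at -0.37, and after upper-quartile scaling 13 genes reached 0.4 and 0 reached -0.4. The next highest were Serinc5, Unc5b, Bmp6, Crispld1, Myo6, Cep85l, Panx3, Mettl10, Cpe, Ugp2, Eps8l2, Ptgis and Pmp22, down to 0.36. The next lowest were Prelp, Actr2, Ptges3, Rps25, Srsf2, Trabd2b, Srxn1, Nup98, Golt1b, Arglu1, Rqcd1, Acta2, H19 and Gid4, up to -0.31. With the first principal component of the zone genes as the axis, 74 genes reached 0.4 and 26 reached -0.4 among 5409.

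Mitotic genes were rarely detected. At least 4 of the 15 measured G2/M genes were detected in 9 of 187 profiles (4.81%, interval 2.22 to 8.94%), and Mki67, a proliferation marker, in 18 (9.63%, 5.81 to 14.8%). G2/M-positive profiles made up 3 of the 139 with Col10a1 (2.16%, 0.447 to 6.18%) and 6 of the 48 without it (12.5%, 4.73 to 25.2%), and these intervals overlap. They made up 4.84% of profiles with Ihh and 4.80% of those without. All 187 profiles entered these shares, cluster 5 included, which holds 3 of the 9 G2/M-positive profiles. These contrasts therefore mix cell types. The median number of genes detected was 3810 in G2/M-positive profiles and 3414.5 in the others. For S phase, 74 profiles (39.6%, 32.5 to 47.0%) had at least 4 of 15 genes. This list includes Pcna, which was detected in 82.4% of profiles, and the share was 16.0% with detection set at a value of 10.

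Ihh and Col10a1 were detected together in 54 profiles, where 46.1 were expected if the detections were independent, a ratio of 1.17. Of the 62 profiles with Ihh, 87.1% had Col10a1 (interval 76.1 to 94.3%), against 68.0% (59.1 to 76.1%) of the 125 without Ihh. Ibsp and Spp1 were detected together in 27 profiles, where 12.5 were expected, and Ibsp and Mmp13 in 11, where 4.18 were expected. The profiles with Ihh had a median of 3689 genes detected and those without 3294. All profiles entered these counts, cluster 5 included, so that the co-detections mix cell types. Ibsp was detected in 83.3% of the profiles of cluster 5 and 20.6% of the others, and Spp1 in 75% and 24%. Outside cluster 5, Ihh was detected in 34.9% of profiles and Col10a1 in 77.7%. Co-detection without cluster 5 was not computed. In the mm10 build, as annotated by GENCODE M21, Col10a1 (ENSMUSG00000039462.4) lies on chromosome 10 at 34389981 to 34397085, and Ihh (ENSMUSG00000006538.12) on chromosome 1 at 74945315 to 74951672, both protein-coding.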

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

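Every test in this part was chosen after the result was seen. One column outside the comparisons of the report, Cell_204, held a signal of its own: 5073 genes were detected in it, more than in any of the 187 profiles. It correlated with the repeat set of Cell_148 and Cell_152 (r = 0.868) and with that of Cell_018 and Cell_065 (0.861), which correlated with each other at 0.614. A sum of both profiles with weights of 60.9% and 39.1% gave the column at r = 0.987, above the lowest value between repeats of 0.964. With both profiles left out, an equal mixture of any 2 others reached at most 0.729. That low value was to be expected, and pairs with 1 of both profiles or with fitted weights were not tried. The correlations of 0.868 and 0.861 argue against 2 further cells caught together, since different profiles correlated with each other at no more than 0.686. They and the fitted sum go with material of these 2 cells mixed after cDNA synthesis. Whether the mixing arose at the bench or in the files stays open, and no biological explanation was tested.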

How the results depend on the processing

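The settings that keep repeat columns apart or add the mixed column were chosen after the data were seen, as were those for leading genes, 1 of which leaves out cluster 5. Sequencing depth is unknown, so what depth limits could be judged only through genes detected. No paired analysis was possible because there is 1 group and no test. Of the 64 values of the comparisons under other settings, 20 moved, and a change of direction was not scored. The other 44 stayed within 1 SD (over profiles or resamples), the counting interval or, for counts, 1.5 times the reported value. The cause was not tested except where the setting itself removes values. With detection at a value of 10, which removes low values, the median of genes detected was 2470, the share for other cell types 8.56%, the S phase share 16.0% and the Ihh and Col10a1 ratio 1.31; with any value above 0 the ratio was 1.11. The number of clusters was 3 with a pseudocount of 0.1, 3 without cell cycle genes, 3 with genes detected regressed out, 7 with 2000 variable genes (adjusted Rand index 0.516), 4 with the mixed column (0.447) and 8 with repeats kept apart, where 28 of 33 columns of cluster 3 lay in a cluster of 71. The resting and hypertrophic correlation was 0.0175 given genes detected and 0.301 after upper-quartile scaling. Genes with rho of at least 0.4 and at most -0.4 numbered 1 and 0 with all cells, 74 and 26 with the first component of the zone genes, 1 and 0 given genes detected, and 13 and 0 after upper-quartile scaling; 5 reached 0.4 with repeats kept apart. Of the 10 leading genes, 4 to 9 stayed for cluster 1, 5 to 10 for cluster 2, 7 to 10 for cluster 3 and 1 to 8 for cluster 4 over 6 settings, and 8 to 10 for cluster 5 over 5. Of 54 values of single lists along the axis, 41 stayed outside the random range and 13 did not: 5 of TGF-beta, 3 of BMP, 2 of immediate-early, 2 of mineralization and 1 of S phase genes.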

Other observations

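The tests in this part were chosen after the results were seen. The hypertrophic-like cluster 3 had genes with large differences at its low end. Spry2 was lower by a difference of -4.38 (2.44 against 6.82 in all other profiles), Foxn2 by -3.45, Rbm26 by -3.44, Arglu1 by -3.43, Il11, a cytokine gene, by -3.13, Lmna by -2.98 and Hmga2, a chromatin protein gene, by -2.92. Sox9 averaged 6.58 ± 1.18 SD in cluster 3, 9.09 ± 1.03 in cluster 1 and 9.17 ± 0.99 in cluster 2, while Acan averaged 9.74, 9.18 and 8.87. Frzb, a secreted WNT antagonist, was higher in cluster 3 by 3.22 and Gadd45g by 3.28.

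In cluster 2, genes picked for their function after their values were seen included Il11, higher by 2.06, Hbegf, an EGF family growth factor, by 2.03, and Cthrc1 by 2.12. Inhba, the activin subunit gene and one of its leading genes, averaged 6.39 ± 3.47 SD against 4.06. In the osteoblast-like cluster 5, Ifitm5 was higher by 4.81 and Spp1 by 4.34, and at least 4 G2/M genes were detected in 3 of its 12 profiles (interval 5.49 to 57.2%). The counts were 4 of 62 in cluster 2 (1.79 to 15.7%), 1 of 30 in cluster 3 (0.0844 to 17.2%) and 1 of 16 in cluster 4 (0.158 to 30.2%), whose intervals overlap that of cluster 5, and 0 of 67 in cluster 1, which allows a share of up to 5.36%. The G2/M list was higher in cluster 5 by a median of 0.59 (15 of 15 genes) and the S phase list by 0.40 (12 of 15), above upper random limits of 0.29 and 0.32. Those limits do not allow for genes that vary together, so the 15 genes are not separate observations. Along the first component of the zone genes, which correlated with genes detected at rho = 0.48, Ccdc80 (0.70), Dap (0.62) and Cpe (0.62) were highest and Lmna (-0.57), Arglu1 (-0.55) and Ptges3 (-0.53) lowest; given genes detected, 27 genes reached 0.4 and 19 reached -0.4.

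The columns that were nearly the same were weighed against similar cells of one type. With pairs chosen on every other gene, at most 8.53% of the genes of middling detection that were not used were detected in only 1 column, whereas the lowest value in the other pairs was 27.6%. This gap argues against a graded likeness between cells of one type as the source. The low values are consistent with cDNA of one cell sequenced or listed more than once. The labels give no reason for it, and no biological explanation was tested.

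Col2a1 near the floor was weighed as well. Few chondrocytes among the cells cannot account for it, since Acan was detected in 94.7% of profiles and Col2a1 in 20.3%. Quantification that fails for genes of very high coverage could leave an abundant gene near 0. Of the chondrocyte list, 3 genes never reached 4, namely Col2a1, Sox5 and Sox6, and the latter are regulators that may be scarce in any case, so that this explanation cannot be told apart from low values of other origin without the reads.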
